A study of Mus musculus with 32 samples.

How the data were processed

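Mesenteric arterial trees of eET-1 and wild-type mice of both sexes and 2 ages were hybridised to Illumina bead arrays, 32 in all, with 4 arrays in each of 8 groups. Per the labels, tissue was kept in RNAlater, fat was removed in it, RNA was extracted with Trizol and columns, and biotin-labelled cRNA was made. The deposited tables hold the mean bead intensity of each probe on each array, neither background-subtracted nor normalised, from 35.45 to 70310. The deposited tables also give a detection p-value of each probe on each array, against negative control beads. The authors' own normalised values are on the log2 scale, made with RMA per the submitters' processing notes, and their exact steps, their version and the genome build of the probe coordinates are not given in the sources used here. On each array the authors' values order the probes as the signals do (Spearman 1). A further 176 per-sample columns in 4 files were not used.

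Signal columns were matched to samples by cohort and sample number. Each cohort was normalised alone with limma 3.58.1 in R 4.3.3: background correction and quantile normalisation with neqc, using detection p-values in place of control probes, with an offset of 16. Probes with a detection p under 0.01 on at least 4 of the 8 arrays of a cohort were kept. The 25697 probes were joined to 18192 genes by Entrez number (16938 probes), RefSeq number (4666), symbol (2295) or the file's own name (1798), and the probe of highest mean stood for its gene. Of the genes tested, 110 to 161 in a cohort carry an older symbol of another tested gene and so count 2 times. Sex-linked genes were read on each array against the labelled sex.

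Limma's linear model with empirical Bayes moderation tested eET-1 minus wild type within each cohort, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A joint model with a mean for each of the 8 groups tested the mean of the 4 cohort differences and 4 differences between cohort differences: sex at maturity, age in males, age in females and sex in youth. Values are log2 differences, and SE is the moderated standard error. Fold changes of each pair of cohorts were correlated across genes and set against splits of the arrays of both cohorts. List means were tested by permuting genotype within cohorts, exactly with 70 labelled splits for a cohort (smallest two-sided p 0.0286). Differences between cohorts were tested exactly over all pairs of such splits, and the mean of the cohorts with 1e+05 draws.

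There were 38 gene lists, fixed before the data were examined: 21 programmes, 15 cell types and 2 sex checks. The programmes were the endothelin system, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, lipid uptake, NADPH oxidase, antioxidant genes, inflammatory genes, the interferon response, extracellular matrix, vascular tone, renin-angiotensin genes, hypoxia and angiogenesis, the cell cycle, the unfolded protein response, heat shock, immediate early genes, clock activators, clock outputs and the glucocorticoid response. The cell types were smooth muscle, endothelium, white and brown adipocytes, lymphocytes, macrophages, neutrophils, mast cells, pancreatic acinar cells, intestinal epithelium, nerve, skeletal muscle, mesothelium, fibroblasts and erythroid cells. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Tests of the lists for the differences between cohorts were added after the data were seen. Of the list symbols, 5 were renamed to the current symbols of a RefSeq gene reference, which also named the genes joined by Entrez or RefSeq number.

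Named genes were fixed by rule: the 10 past the threshold with the largest difference in each direction, or, where fewer passed, the 5 of smallest p in each direction, with the endothelin genes, the sex-linked genes and the 4 members of smallest p from each list called. Clone names, 3 in all, were passed over. Some genes that the rule names are not reported. Genes named because a single array's omission or array weights gave a call were chosen after their values were seen.

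The titles number the replicates from 1 to 4 in each group. In young females the residuals of like-numbered eET-1 and wild-type arrays correlated at 0.650, 0.472, 0.531 and 0.656, in mature females at 0.273, 0.391, 0.113 and 0.179, and in young males at 0.352, 0.475, 0.396 and 0.519. All exceeded 0.1, so a fit with the replicate number as a block is given beside each result whose call it changes. In young females eET-1 replicates 2 and 3 correlated best with wild-type replicates 4 (0.69) and 1 (0.546). In mature females eET-1 replicates 3 and 4 did so with wild-type replicates 4 (0.275) and 1 (0.187). A shared number may therefore not mark a pair. The block of the joint model covers mature males too, where numbers do not pair the arrays.

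Alternatives were the authors' RMA values, no background correction, normexp with an offset of 50, median centring, no filter on dim probes, detection on all 8 arrays, a variance trend with robust moderation, array weights, the replicate block, age as a covariate, all probes, other thresholds and omission of each array. The pipeline was tested on simulated data: arrays drawn at random from each gene's mean and spread, independently of other genes, with known changes added to 200 genes. Of genes changed 2-fold, 58.2% were called in young females, 61.2% in mature females, 44.8% in young males, 82.1% in mature males and 97.0% in the mean of the cohorts. At 1.5-fold these shares were 17.9%, 29.9%, 11.9%, 59.7% and 86.6%. Genes vary together on the real arrays, so the shares of real changes called may differ.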

Results

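Total RNA of the mesenteric arterial tree, the vessels that feed the gut, was profiled on 32 Illumina bead arrays. The mice were of the C57BL/6 strain. The transgenic mice, called eET-1, overexpress human preproendothelin-1, the precursor of the vasoconstrictor peptide endothelin-1, in the endothelium. Wild-type littermates served as controls. The 4 cohorts were young females, mature females, young males and mature males, each with 4 eET-1 and 4 wild-type arrays. Young mice were 6 to 7 weeks old. In mature males the wild types were 7 to 7.7 months old and the eET-1 mice 6.4 to 6.7 months, so genotype and age ran together there. In young females 3 of 4 eET-1 mice and 1 of 4 wild types were 7 weeks old and the rest 6, so age and genotype were partly mixed. Arrays of young females detected 10417 to 11051 probes, those of mature females 13566 to 14356, those of young males 11342 to 12545 and those of mature males 12529 to 13150. The number of arrays limits the precision of every value. The labels do not state that each array is a separate mouse, so the p-values measure the spread between these samples. Young females were deposited under another platform entry with the same 25697 probes, and each test sets eET-1 against wild type within a cohort.

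The probe of mouse Edn1, the endothelin-1 gene, was detected on all 32 arrays. The mouse Edn1 probe read 10.81 ± 0.64 (SD, n = 4) on the log2 scale in eET-1 and 11.45 ± 0.59 in wild-type arteries of young females, and 10.67 ± 0.77 against 11.30 ± 0.33 in mature males. Its log2 difference was -0.64 (SE 0.37) and -0.63 (SE 0.35) in those cohorts, -0.23 (SE 0.20) in mature females and -0.16 (SE 0.26) in young males, and none passed. Without eET-1 replicate 4 the Edn1 difference of mature males was -0.25. In young males its direction turned under the omission of a single array. Whether this probe also reads the human transgene is not stated, so it checks no genotype label. Receptors were abundant: Ednra, the endothelin A receptor of smooth muscle, lay between 10.87 and 11.72 as group means, and the brightest probe of Ednrb, the endothelin B receptor, between 11.90 and 12.40. Other Ednrb probes were dimmer, with group means of 9.32 to 10.35 and of 6.028 to 6.755. Edn2, Edn3 and Kel, a peptidase that processes Edn3, were detected on 0 arrays. In mature males 3 members of the endothelin list passed when adjusted over the list alone. These were Mme, the endothelin-degrading enzyme neprilysin, at 0.70 (SE 0.17), the peptidase Phex at -0.55 (SE 0.10) and the converting enzyme Ece2 at 0.31 (SE 0.11). None of them passed over all genes.

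The sex labels were compared with sex-linked genes. The Y-linked genes Eif2s3y and Kdm5d were detected on 16 male and 0 female arrays. Xist, the transcript of the inactive X chromosome, was detected on 16 female and 0 male arrays. The Uty probe was detected on 16 male and 9 female arrays, and a Ddx3y probe on all, at 11.39 to 12.51 in males and 9.43 to 10.48 in females.

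The first comparisons asked which transcripts differ between transgenic and wild-type arteries of 1 age and sex. Genes that build fatty acids were higher as a group in eET-1 arteries of the female young cohort. Of 18 measured members of fatty acid and triglyceride synthesis, 16 had a positive difference, and the list mean was 0.53. Relative to the cohort mean, the list lay at -0.73 on eET-1 replicate 2 and at 0.48 to 0.69 on the other eET-1 arrays. Acly, which makes cytosolic acetyl-CoA from citrate, read 14.04 ± 0.62 against 13.02 ± 0.42 (SD, n = 4), a difference of 1.02 (SE 0.32). Me1, a source of NADPH, differed by 1.36 (SE 0.40), Acss2, which activates acetate, by 1.25 (SE 0.50), and Fasn, fatty acid synthase, by 1.08 (SE 0.37). Limma's camera test gave an adjusted p of 5.20e-07 for the list, against adjusted p = 0.361 with an estimated correlation. Each of these 4 genes was above every wild-type array on 3 of 4 eET-1 arrays, and 0 members passed over all genes or, without the replicate block, when adjusted over the list alone. With the block, 6 passed over the list alone (Acly, Fasn, Me1, Acss2, Lpin1 and Dgat2). Clock outputs were higher in 9 of 9 members with a mean of 0.71 (adjusted p = 4.82e-06, and adjusted p = 0.321 with an estimated correlation), among them Per2, a core repressor of the clock, at 0.91 (SE 0.36). Glucocorticoid-responsive genes were higher in 6 of 6 members with a mean of 0.60 (adjusted p = 7.62e-05, and adjusted p = 0.244 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, led them at 1.80 (SE 0.56). Heat shock genes were higher in 8 of 8 members, with Hsph1 at 0.63 (SE 0.33) and a list mean of 0.37 (adjusted p = 1.72e-05, and adjusted p = 0.244 with an estimated correlation).

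Markers of blood and other cells moved with these groups in young females. Erythroid genes were higher by a mean of 0.85 in 4 of 4 members (adjusted p = 1.03e-06, and adjusted p = 0.244 with an estimated correlation). Slc4a1, the band 3 protein of red cells, was higher by 1.41 (SE 0.45) and passed when adjusted over the list alone, as 4 members did with the replicate block. Macrophage markers had a mean of 0.20 with Cd163 at 0.70 (SE 0.33), immediate early genes 0.25, brown adipocyte markers 0.37, fibroblast markers 0.16 and fatty acid oxidation genes 0.15. The adjusted p was 0.000174, 0.000412, 0.00319, 0.00319 and 0.0320 for these lists in turn, and with an estimated correlation the adjusted p was 0.489, 0.244, 0.361, 0.256 and 0.501. Lower lists were pancreatic acinar markers at -0.34, cholesterol synthesis at -0.21 and lymphocyte markers at -0.27, with adjusted p = 0.000412, 0.00300 and 0.00458, and with an estimated correlation the adjusted p was 0.604, 0.397 and 0.419. Within cholesterol synthesis, Sqle, squalene epoxidase, differed by -0.67 (SE 0.25) and Hsd17b7, a sterol ketoreductase, by -0.46 (SE 0.19). With the replicate number as a block, Cd163 of the macrophage list, Sqle and Msmo1 of the cholesterol list and Cox8b and Cidea of the brown adipocyte list passed over the list alone, and white adipocyte markers also passed (mean 0.15, adjusted p = 0.00916, and 0.262 without the block), with adjusted p = 0.664 with an estimated correlation and the block.

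Among single genes of young females, 0 of 8500 passed limma's adjusted p of 0.05, and 112 had an unadjusted p under 0.05 where chance gives 425 (415 with the replicate block). The smallest p among positive differences belonged to Retnla, a secreted product of alternatively activated macrophages, at 12.83 ± 0.05 against 11.84 ± 0.29 (SD, n = 4). Hs3st3a1, a heparan sulphate sulphotransferase, differed by 0.66 (SE 0.12), the chemokine Ccl6 by 1.04 (SE 0.24), Dfna5h by 0.69 (SE 0.17) and Ppp1r15b by 0.43 (SE 0.11). In the other direction lay Neu2, a cytosolic sialidase, at -0.80 (SE 0.15), the metalloprotease Adam33 at -0.47 (SE 0.11), Relb, an NF-kappaB subunit, at -0.50 (SE 0.15), and the nerve peptides Npy at -0.82 (SE 0.24) and Vip at -0.76 (SE 0.23). Each of these 10 genes separated the 4 eET-1 from the 4 wild-type arrays completely. They were picked for their small p, so the separation is no further evidence.

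Several of the young female list calls rested on few arrays. Replicates 1 and 3 of both genotypes had median signals of 160 to 169 and replicates 2 and 4 of 195 to 203. Camera called 5 lists within replicates 1 and 3 and 13, not all of them the lists called with every array, within replicates 2 and 4. Fatty acid synthesis was called in both sets of this female young cohort (mean 0.48 and 0.58), as were heat shock genes (0.46 and 0.28), while clock outputs (0.16 and 1.26), erythroid markers (0.59 and 1.12) and glucocorticoid genes (0.64 and 0.56) were called within replicates 2 and 4 and not within 1 and 3, as were the cholesterol, macrophage, immediate early and lymphocyte lists. Fibroblast and brown adipocyte lists were called in neither set. Pancreatic acinar markers were lower within replicates 1 and 3 (-1.001) and higher within 2 and 4 (0.32), and fatty acid oxidation genes were called within 1 and 3 (0.31) and had a mean of -0.02 within 2 and 4. The macrophage call ended without eET-1 replicate 1 or wild-type replicate 2 (adjusted p up to 0.457), the acinar call without eET-1 replicate 1 or wild-type replicate 3 (up to 0.787), and the cholesterol call without eET-1 replicate 2 or wild-type replicate 4 (up to 0.311). Immediate early genes lost theirs without wild-type replicate 4 (0.105), fibroblast markers without wild-type replicate 2 or 3 (up to 0.102), and lymphocyte markers without eET-1 replicate 3 or wild-type replicate 2 or 4 (up to 0.290). Brown adipocyte markers lost it without eET-1 replicate 1 or 3 or wild-type replicate 2 or 4 (up to 0.0957), and fatty acid oxidation without eET-1 replicate 1 or 4 or wild-type replicate 1, 2 or 3 (up to 0.665) and with the array set as a block (0.0824). With age as a covariate the immediate early, brown adipocyte and lymphocyte calls ended (0.246, 0.0793 and 0.393). With no filter on dim probes the lymphocyte, brown adipocyte and fatty acid oxidation calls ended (0.177, 0.185 and 0.150), and among probes detected on all 8 arrays the lymphocyte list had too few members to test.

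In mature females, macrophage and proliferation genes were higher in eET-1 arteries and adipocyte markers lower. Macrophage markers were higher in 16 of 16 members with a mean of 0.39. Lyz2, lysozyme of myeloid cells, read 12.29 ± 0.32 against 11.75 ± 0.37 (SD, n = 4), and Ctss, the protease cathepsin S, differed by 0.75 (SE 0.38). Cell cycle genes were higher in 14 of 14 members with a mean of 0.36, led by Tk1, thymidine kinase, at 0.72 (SE 0.22) and Cdk1, the mitotic kinase, at 0.80 (SE 0.37). Camera's adjusted p was 2.89e-09 for macrophage markers and 4.08e-07 for the cell cycle, and both had adjusted p = 0.734 with an estimated correlation. Inflammatory genes had a mean of 0.40 with 10 of 13 members positive, among them the cytokine Il1b at 0.90 (SE 0.38) and the chemokines Cxcl1 at 1.01 (SE 0.45) and Ccl2 at 0.98 (SE 0.46). Nfkbia, an inhibitor of NF-kappaB, lay at -0.27 (SE 0.13). White adipocyte markers were lower in 14 of 14 members with a mean of -0.35. The insulin-responsive glucose transporter Slc2a4 lay at -0.36 (SE 0.12), below every wild-type array on 4 of 4 eET-1 arrays, and the lipase Lipe at -0.53 (SE 0.25). Inflammatory genes had an adjusted p of 0.00373 and adipocyte markers of 1.59e-06, both with adjusted p = 0.734 with an estimated correlation.

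Other cell types moved with them in mature females. Acinar markers of the pancreas were higher by a mean of 0.56 in 13 of 13 members and lymphocyte markers by 0.31 in 11 of 12, with adjusted p = 2.66e-05 and 0.00400. Endothelial markers were lower by a mean of -0.16 in 14 of 16 members (adjusted p = 0.00179), with Vwf, von Willebrand factor, at -0.43 (SE 0.21). Fatty acid and triglyceride synthesis was lower, with a mean of -0.19 and 15 of 18 members negative (adjusted p = 0.00416). Its leading members were Lpin1, a phosphatidate phosphatase, at -0.48 (SE 0.17) and the desaturase Scd2 at -0.42 (SE 0.17). With an estimated correlation each of these 4 lists had adjusted p = 0.734. With the replicate block 4 more lists passed. Mesothelium (mean -0.40, adjusted p = 0.00100, and 0.0806 without the block), clock outputs (-0.29, 0.00108 and 0.130) and the glucocorticoid response (-0.23, 0.00378 and 0.0832) were lower, and erythroid markers (0.26, 0.0440 and 0.273) were higher. Each of these 4 had adjusted p = 0.651 with an estimated correlation and the block. Without wild-type replicate 4 the acinar (adjusted p = 0.348) and endothelial (0.0589) calls ended, and without eET-1 replicate 4 the inflammatory call (0.178), which in this female mature cohort also ended among probes detected on all 8 arrays (0.0543). Lymphocyte markers lost theirs without eET-1 replicate 1 or 4 or wild-type replicate 1 (up to 0.437), and fatty acid synthesis without eET-1 replicate 3 or wild-type replicate 1 or 4 (up to 0.573) and with age as a covariate.

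For single genes of mature females, limma called 0 of 10637, with 212 at an unadjusted p under 0.05 where chance gives 532 (308 with the replicate block). The smallest p values belonged to Klf15, a transcription factor of metabolic genes, at -0.70 (SE 0.14), then Wdfy3 at -0.56 (SE 0.14), the Wnt co-receptor Lrp6 at -0.70 (SE 0.18), the glycosyltransferase Mgat1 at -0.47 (SE 0.12) and Tbc1d10b at -0.51 (SE 0.14). On the positive side stood Snapc2 at 0.55 (SE 0.13), Dcx at 0.50 (SE 0.13), the Toll-like receptor adaptor Ticam2 at 0.55 (SE 0.15), Csf3r, the receptor of granulocyte colony-stimulating factor, at 0.51 (SE 0.14) and Tns4 at 0.52 (SE 0.15).

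In young males, lipid synthesis genes were higher in eET-1 arteries, as were clock activators and smooth muscle genes. All 18 members of fatty acid and triglyceride synthesis were positive, with a mean of 0.49. Scd1, the main stearoyl-CoA desaturase, read 15.01 ± 0.60 against 14.19 ± 0.45 (SD, n = 4). Fads2, a desaturase of polyunsaturated fatty acids, differed by 0.52 (SE 0.19), and Srebf1, which encodes a master regulator of these genes, by 0.55 (SE 0.23). Cholesterol synthesis had 13 of 16 members positive with a mean of 0.34, including Insig1, the sterol sensor that retains SREBP in the endoplasmic reticulum, at 0.52 (SE 0.20), Sqle at 0.55 (SE 0.22) and Msmo1 at 0.51 (SE 0.20). For these lists the adjusted p was 6.61e-09 and 8.04e-05, and both had adjusted p = 0.637 with an estimated correlation. No member of either passed over the list alone without the replicate block, and with it 12 and 4 did. Clock activators were higher in 4 of 4 members with a mean of 0.96, with Arntl, the BMAL1 gene, at 1.24 (SE 0.56). Clock outputs were lower in 8 of 8 with a mean of -0.63, with Dbp at -1.57 (SE 0.94). These lists had adjusted p = 0.00167 and 0.0297, and with an estimated correlation adjusted p = 0.637 and 0.766. Contractile genes of smooth muscle were positive in 14 of 15 members with a mean of 0.24 (adjusted p = 0.00198, and adjusted p = 0.649 with an estimated correlation). Among them Synpo2, an actin-bundling protein, differed by 0.81 (SE 0.17), was above every wild-type array on 4 of 4 eET-1 arrays and passed when adjusted over the list alone.

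Fat and blood markers moved in the same direction as the lipid genes of young males. White adipocyte markers had a mean of 0.28 in 13 of 13 members and brown adipocyte markers 0.43 in 5 of 5, and erythroid markers 0.46 in 5 of 5. Their adjusted p was 0.00388, 0.0337 and 0.0297, and with an estimated correlation the adjusted p was 0.672, 0.649 and 0.672. Hypoxia and angiogenesis genes had a mean of 0.27 with Hk2, hexokinase 2, at 0.59 (SE 0.23) and Angpt2 at -0.44 (SE 0.16), and vascular tone genes a mean of 0.16 with Rgs2 at 0.56 (SE 0.31). Lymphocyte markers lay at -0.49 in 8 of 8 members and acinar markers at -0.36 in 11 of 13. The adjusted p of these 4 lists was 0.0166, 0.0337, 0.0297 and 0.0424, and with an estimated correlation the adjusted p was 0.637, 0.781, 0.766 and 0.839. With the replicate block the glucocorticoid response passed too (mean -0.38, adjusted p = 0.0255, and 0.158 without the block), and over their lists alone all 4 clock activators, Slc4a1 and Ppargc1a. The glucocorticoid list had adjusted p = 0.623 with an estimated correlation and the block. In this male young cohort eET-1 replicate 4 stood apart, at -62.5 on a first principal component with 50.2% of the variance, where the other 7 arrays lay from -13.7 to 20.9. Without it the list means were 0.35 for fatty acid synthesis, 0.34 for cholesterol synthesis, 0.83 for clock activators and 0.15 for smooth muscle, all 4 still called. Single arrays and processing choices ended many calls of young males. Smooth muscle lost its call without wild-type replicate 1 (adjusted p = 0.142), hypoxia without wild-type replicate 3 (0.0591), and white adipocyte markers without eET-1 replicate 1 or 2 or wild-type replicate 2 (up to 0.191). Clock outputs (up to 0.451) and brown adipocyte markers (up to 0.764) lost theirs without eET-1 replicate 1, 2 or 3 or wild-type replicate 2 or 3. Erythroid markers did without eET-1 replicate 1, 2 or 3 or wild-type replicate 1 or 4 (up to 0.336), lymphocyte markers without eET-1 replicate 2, 3 or 4 or wild-type replicate 1 or 3 (up to 0.380), and vascular tone without eET-1 replicate 3 or 4 or wild-type replicate 1 or 2 (up to 0.462). The acinar list lost its call without eET-1 replicate 1 or wild-type replicate 1, 2 or 3 and had a mean of -0.02 without eET-1 replicate 4 (up to 0.904). With the authors' RMA values the brown adipocyte, acinar and vascular tone calls ended (each 0.0531), with no filter on dim probes the lymphocyte (0.0571) and acinar (0.0591) calls, and among probes detected on all 8 arrays the brown adipocyte call (0.303), where lymphocyte markers had too few members to test.

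Of single genes in young males 0 of 9247 passed limma's test, and 226 had an unadjusted p under 0.05 where chance gives 462 (631 with the replicate block). Besides Synpo2 the genes of smallest p were Tnfrsf22, a decoy receptor of the tumour necrosis factor family, at 0.71 (SE 0.16), Hadh, a fatty acid oxidation enzyme, at 0.55 (SE 0.13), Erp44 at 0.58 (SE 0.18) and the glycolytic enzyme Pfkp at 0.49 (SE 0.15). Negative differences were led by the homeobox gene Barx1 at -1.19 (SE 0.25) and Gkn3 at -1.19 (SE 0.26), followed by the protease inhibitor Serpina1e at -0.81 (SE 0.21), Vps37d at -0.92 (SE 0.25) and Cd163l1 at -0.59 (SE 0.16).

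In mature males, both lipid synthesis lists were higher in eET-1 arteries. Fatty acid and triglyceride synthesis was higher in 18 of 18 members by a mean of 0.99, and 11 members passed when adjusted over the list alone. Dgat2, which makes triglyceride, read 14.09 ± 0.29 against 13.05 ± 0.48 (SD, n = 4), Fasn differed by 1.56 (SE 0.39), Acly by 1.499 (SE 0.38) and Srebf1 by 0.81 (SE 0.22). Cholesterol synthesis was higher in 14 of 15 members by a mean of 0.62, and 12 members passed when adjusted over the list alone. Insig1 differed by 1.30 (SE 0.26), Cyp51, lanosterol demethylase, by 1.00 (SE 0.23), Fdps, farnesyl diphosphate synthase, by 0.72 (SE 0.17) and Dhcr7, the last enzyme of the pathway, by 0.71 (SE 0.14), each above every wild-type array on 4 of 4 eET-1 arrays. Both lists had an adjusted p of 1.97e-11, and adjusted p = 0.758 with an estimated correlation. A two-sided exact permutation test of the list mean gave p = 0.0286 for cholesterol synthesis, the smallest this design allows, and p = 0.0857 for fatty acid synthesis. Neither passed adjustment over the lists, which this design allows only if many lists reach the smallest p together.

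Contractile and vascular tone genes were lower in the same mature male arteries. Smooth muscle genes had a mean of -0.21 with 15 of 16 members negative. The intermediate filament Des at -0.38 (SE 0.08) and Myocd, the coactivator that drives the contractile programme, at -0.85 (SE 0.20) passed when adjusted over the list alone. Vascular tone genes had a mean of -0.24 with 18 of 23 negative. Rgs5, which dampens G protein signalling in mural cells, lay at -1.42 (SE 0.39), Prkg1, the cGMP-dependent kinase, at -0.60 (SE 0.18), Abcc9, a subunit of the ATP-sensitive potassium channel, at -0.42 (SE 0.12) and the prostacyclin receptor Ptgir at -0.29 (SE 0.10). Clock outputs were lower in 9 of 9 members with a mean of -1.07, including Dbp at -2.34 (SE 1.11) and Nr1d1, the REV-ERB alpha gene, at -1.68 (SE 0.64). The adjusted p was 0.000201, 0.000248 and 0.00419, and each of the 3 lists had adjusted p = 0.758 with an estimated correlation. Alongside them acinar markers were lower by a mean of -1.08 in 13 of 13 members, white adipocyte markers higher by 0.39 in 12 of 13 with Adipoq, adiponectin, at 0.46 (SE 0.15), and nerve markers higher by 0.45 in 4 of 5. Relative to the cohort mean, acinar markers lay at 0.61, -0.41, -0.69 and -1.67 on eET-1 replicates 1 to 4. On wild-type replicates 1 to 4 they lay at 1.47, -0.02, -0.86 and 1.57. The myelin genes Mbp at 0.51 (SE 0.13) and Cnp at 0.43 (SE 0.18) passed when adjusted over the list alone. Oxidative phosphorylation genes were higher by a mean of 0.12. These lists had adjusted p = 0.000266, 0.000931, 0.00120 and 0.0198, and adjusted p = 0.758 with an estimated correlation. With age as a covariate the smooth muscle, vascular tone, adipocyte and oxidative phosphorylation calls ended. The last also ended without eET-1 replicate 3 or 4 or wild-type replicate 4 (adjusted p up to 0.228) and, in this male mature cohort, with median centring (0.105).

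By single genes of mature males, limma called 0 of 9675, the lowest adjusted p was 0.111, and 1077 had an unadjusted p under 0.05 where chance gives 484. Array weights gave 9 genes. Without eET-1 replicate 1, 85 genes passed, 66 higher and 19 lower (84, of which 65 higher, when Mod1, an older symbol of Me1, is counted with it). Among the genes of smallest p were the sulphotransferase Chst8 at -0.87 (SE 0.11), the dynein light chain Dynll2 at -0.67 (SE 0.09), Lrfn3 at -0.53 (SE 0.07) and the kinase Pim3 at -0.80 (SE 0.11). On the positive side were the semaphorin receptor Plxnb3 at 0.66 (SE 0.11), the fatty acid carrier Fabp5 at 1.16 (SE 0.21), Nudcd2 at 0.39 (SE 0.07), Sntb1 at 0.51 (SE 0.10) and Scg3 at 0.64 (SE 0.12). Each of these genes separated the genotypes completely, which their choice by small p favours, so it is no further evidence.

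**Figure D1:**
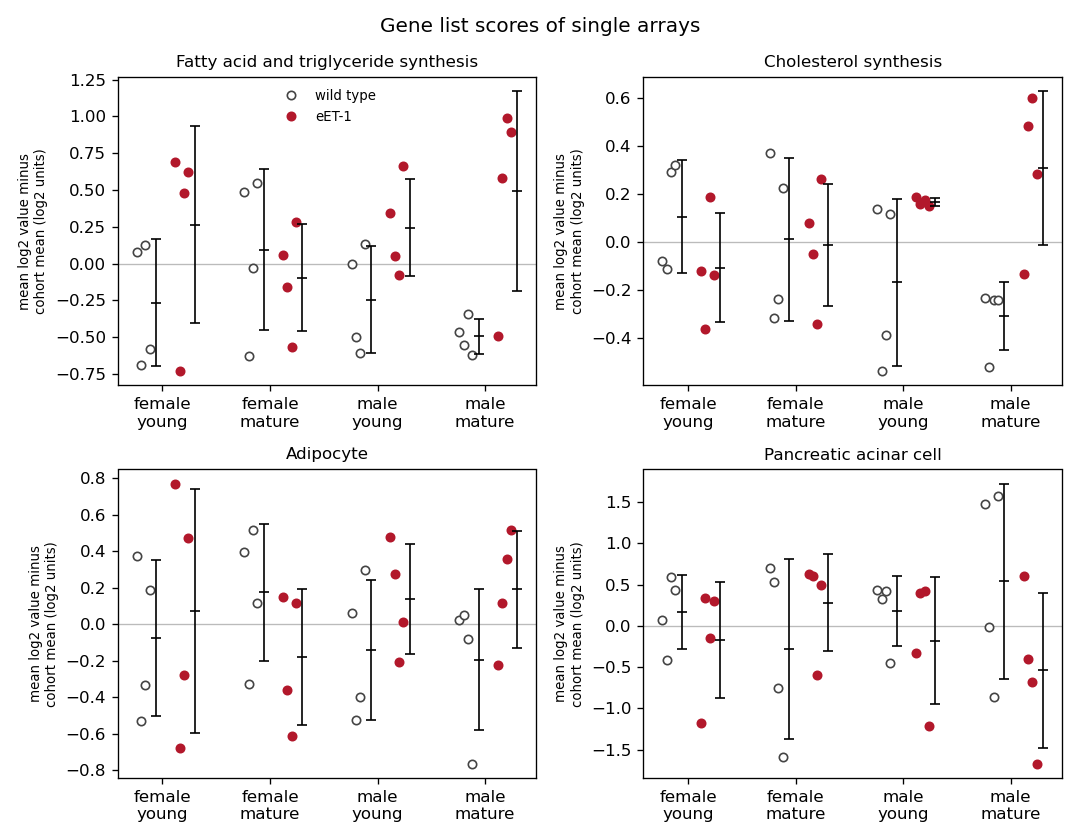
Each point is 1 array: the mean log2 value of a gene list minus the mean of its cohort, in log2 units, for 4 lists (panels) and 4 cohorts (horizontal axis), with open points for wild type and filled points for eET-1. Bars give mean ± SD (n = 4). In mature males 4 of 4 eET-1 arrays lie above all wild types for cholesterol synthesis and 3 of 4 for fatty acid synthesis, and in young females eET-1 replicate 2 lies at -0.73 for fatty acid synthesis.

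In the mean of the 4 cohorts, fatty acid synthesis genes were higher in eET-1 arteries, although in mature females they were lower (mean -0.19, 15 of 18 members negative). Plin2 (probe ILMN_1222246), which coats lipid droplets, differed by 0.57 (SE 0.11) as the mean of 4 cohorts (adjusted p = 0.0684), positive in 4 of 4 cohorts. It passed with the replicate block (adjusted p = 0.0146), which also blocks mature males, where numbers do not pair the arrays. Its difference was 0.66 (SE 0.20) in young females, 0.09 (SE 0.17) in mature females, 0.54 (SE 0.21) in young males and 1.00 (SE 0.21) in mature males. Fatty acid and triglyceride synthesis was higher in 18 of 18 members by a mean of 0.45, and Acly at 0.76 (SE 0.21), Fasn at 0.76 (SE 0.22), Me1 at 0.80 (SE 0.23) and Scd1 at 0.65 (SE 0.20) were among the 8 that passed when adjusted over the list alone (9 with the block). Camera gave an adjusted p of 4.28e-15, against adjusted p = 0.32 with an estimated correlation, and the permutation test of the list mean gave p = 0.0185 before adjustment over the lists. Ddah1 (probe ILMN_1256676), which degrades the nitric oxide synthase inhibitor asymmetric dimethylarginine, lay at -0.61 (SE 0.13, adjusted p = 0.198). Its difference was -0.55 (SE 0.23), -0.45 (SE 0.17), -0.71 (SE 0.26) and -0.72 (SE 0.27) in young females, mature females, young males and mature males.

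Cholesterol synthesis was higher over the cohorts by a mean of 0.17, erythroid markers by 0.45, macrophage markers by 0.15, brown adipocyte markers by 0.24 and white adipocyte markers by 0.14, and acinar markers were lower by a mean of -0.31. Lss, lanosterol synthase, differed by 0.46 (SE 0.18), Slc4a1 by 0.76 (SE 0.27), Lyz2 by 0.31 (SE 0.11) and Adgre1, the F4/80 antigen of macrophages, by 0.32 (SE 0.13). In the order given the adjusted p was 0.000164, 0.000168, 0.000164, 0.0212, 0.0216 and 0.00514, and with an estimated correlation the adjusted p was 0.401, 0.401, 0.560, 0.560, 0.747 and 0.747. With the replicate block 5 cholesterol, 4 erythroid and 4 macrophage genes passed over the list alone, against 0, 1 and 0 without it. The cholesterol call ended without either male cohort, the erythroid call without young females and the macrophage call without mature females. The acinar call ended without young females or mature males, and both adipocyte calls without young females, young males or mature males. Both adipocyte calls also ended with no filter on dim probes, and the brown one among probes detected on all 8 arrays. Omitting 1 array ended the acinar call for young female eET-1 replicate 1, mature female eET-1 replicate 3 and wild-type replicate 1, and mature male eET-1 replicate 4 and wild-type replicates 1 and 4 (adjusted p up to 0.121). The brown adipocyte call ended without young female eET-1 replicate 1 or 3 or wild-type replicate 2 or 4, mature female eET-1 replicate 1, young male eET-1 replicate 2 or mature male eET-1 replicate 3 (up to 0.209). White adipocyte markers lost theirs without any 1 of 13 arrays: eET-1 replicates 1 and 4 and wild-type replicate 2 of each female cohort, eET-1 replicates 1 and 2 and wild-type replicates 2 and 3 of young males, and eET-1 replicates 3 and 4 and wild-type replicate 4 of mature males (up to 0.239).

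No gene passed limma's test among 8386 in the mean of the cohorts without the block, and 318 had an unadjusted p under 0.05 where chance gives 419 (756 with it). Plin2 passed without young female eET-1 replicate 2 (adjusted p = 0.0254), mature female wild-type replicate 4 (0.0490), young male wild-type replicate 1 (0.0216), mature male eET-1 replicate 1 (0.0457) or mature male wild-type replicate 2 (0.0301). Ddah1 passed without young male wild-type replicate 3 (0.0497) or mature male eET-1 replicate 1 (0.0457). Others of small p were Dfna5h at 0.34 (SE 0.08), the glycolytic enzyme Eno1 at 0.25 (SE 0.07), Cracr2b, a regulator of store-operated calcium entry, at -0.33 (SE 0.07), Gkn3 at -0.68 (SE 0.18), Gas6, a ligand of TAM receptors, at -0.30 (SE 0.08) and Iyd at -0.51 (SE 0.14).

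**Figure D2:**
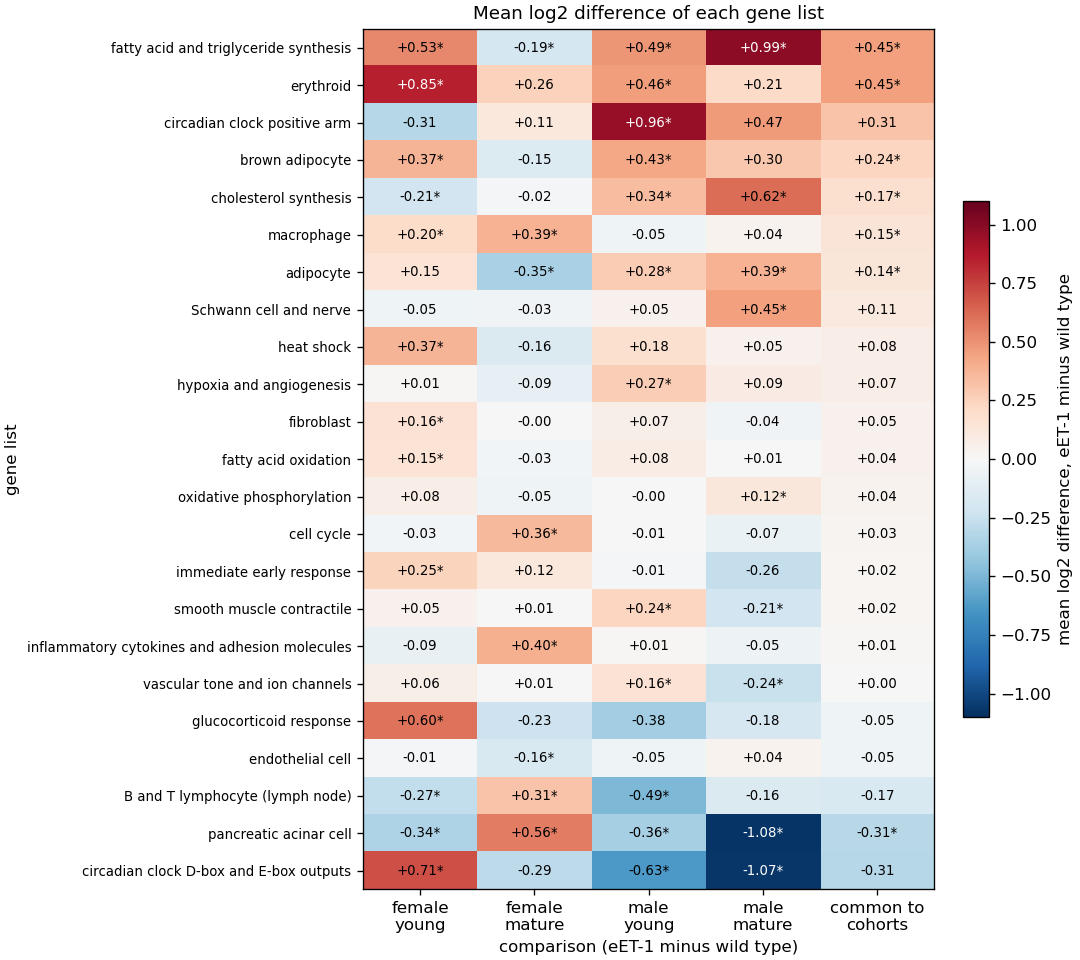
Mean log2 difference, eET-1 minus wild type, of each gene list (rows) called in any cohort or in the mean of the cohorts (columns), with red for higher and blue for lower in eET-1. A star marks a camera adjusted p under 0.05 at the preset correlation. Fatty acid and triglyceride synthesis stands at 0.53, -0.19, 0.49 and 0.99 in the 4 cohorts and 0.45 in their mean.

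With an estimated correlation camera called 0 lists in any of the 9 comparisons, and limma's fry test called 0. Permutation of list means also called 0 after adjustment over the lists. Within a cohort its p cannot fall below 0.0286, so a list could pass only if many lists reached that floor together. For single cohorts the 0 is therefore no evidence against a shift. The smallest unadjusted permutation p was 0.0571 in young females and in mature females. The remaining lists were not called in any cohort or in the mean of the cohorts. Their mean log2 differences over the cohorts were -0.10 for the endothelin system (adjusted p = 0.200), 0.02 for lipid uptake (0.617), 0.01 for NADPH oxidase (0.862), -0.02 for antioxidant genes (0.678), 0.05 for the interferon response (0.361), 0.00 for extracellular matrix (0.617), 0.02 for renin-angiotensin genes (0.678), -0.05 for the unfolded protein response (0.785), -0.14 for mast cells (0.373) and -0.19 for mesothelium (0.678), which passed in mature females with the block alone. Neutrophil markers were tested in 3 cohorts, with an adjusted p of 0.383, 0.725 and 0.534 in mature females, young males and mature males. Skeletal muscle markers were tested in mature females (adjusted p = 0.901). Intestinal epithelium had too few detected members to test.

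The difference between genotypes was set against sex at maturity, and camera at the preset correlation called lipid lists among others. Mature females of both genotypes were 6.6 to 6.8 months old, so the age gap of mature males enters this comparison. Female minus male, the difference was -1.18 for fatty acid and triglyceride synthesis, with 18 of 18 members negative, -0.54 for cholesterol synthesis, with 11 of 12 negative, and -0.78 for white adipocyte markers, with 12 of 12 negative. Acinar markers differed by 1.64 with 13 of 13 members positive, and cell cycle genes by 0.40 with 8 of 8 positive. In that order the adjusted p was 6.26e-19, 2.58e-07, 9.98e-09, 2.40e-16 and 0.000181, and with an estimated correlation the adjusted p was 0.143, 0.152, 0.182, 0.152 and 0.182. Permutation of the genotype labels gave p = 0.0408 for fatty acid synthesis and 0.0371 for adipocyte markers, neither passing adjustment over the lists. Genes of smallest p included Aacs, which feeds ketone bodies into lipid synthesis, at -1.74 (SE 0.54), Tmem79 at -2.24 (SE 0.71), the mTOR inhibitor Deptor at -0.65 (SE 0.17), Ppp2r5a at -0.72 (SE 0.21) and Sbk1 at -1.09 (SE 0.35). In the other direction were H2-Q1 at 0.74 (SE 0.19), Scn3b at 0.77 (SE 0.23), the islet transcription factor Isl1 at 1.33 (SE 0.41), Id2 at 0.82 (SE 0.26) and P2ry6 at 0.68 (SE 0.22). Over the list alone 0 members of these lists passed without the replicate block, and with it 14 of fatty acid synthesis, 12 acinar genes and 6 of cholesterol synthesis. Limma called 0 of 8386 genes, with 208 at an unadjusted p under 0.05 (451 with the block). Camera called 18 lists, of which 5 were called under every omission of 1 array and the rest were not, and with the block the brown adipocyte list was lost (mean -0.45, adjusted p = 0.0510) and lipid uptake gained (-0.25, 0.0348, and adjusted p = 0.297 with an estimated correlation and the block).

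In males, the genotype difference of contractile genes was positive in youth and negative at maturity. Mature minus young, smooth muscle genes differed by -0.44 with 15 of 15 members negative and vascular tone genes by -0.39 with 21 of 22 negative. The adjusted p was 2.96e-07 and 2.80e-05, and both had adjusted p = 0.590 with an estimated correlation. A permutation test of the list mean gave p = 0.0171 for smooth muscle, which did not pass adjustment over the lists. Des differed by -0.73 (SE 0.24) and, with Synpo2, passed over the list alone with the replicate block. Further genes of small p were Ttc37 at -0.76 (SE 0.21), Nacad at -0.68 (SE 0.21), Foxk1 at -0.96 (SE 0.31), the growth factor Hbegf at -0.57 (SE 0.19), and on the positive side Rbks, ribokinase, at 0.88 (SE 0.25), Tceanc2 at 0.70 (SE 0.21), D4Ertd22e at 0.73 (SE 0.23), Ppcs, an enzyme of coenzyme A synthesis, at 0.51 (SE 0.17) and Deptor at 0.50 (SE 0.17). Limma called 0 of 8386 genes, with 199 at an unadjusted p under 0.05 (532 with the block). The mature males' age gap between genotypes enters this comparison. Camera called 4 more lists, acinar markers (-0.72), extracellular matrix (-0.23), antioxidant genes (0.26) and fatty acid synthesis (0.50), and each call ended without some single array (adjusted p up to 0.253, 0.162, 0.255 and 0.285), with adjusted p = 0.793 with an estimated correlation. The antioxidant call also ended with no filter on dim probes and among probes detected on all 8 arrays.

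In females, the genotype difference in fatty acid synthesis, heat shock and glucocorticoid genes was lower at maturity than in youth, and that in cholesterol synthesis higher. Mature minus young, fatty acid synthesis differed by -0.72 with 17 of 18 members negative, heat shock genes by -0.57 with 8 of 8 negative and glucocorticoid genes by -0.82 with 6 of 6 negative. Fkbp5 differed by -2.15 (SE 0.67) and passed when adjusted over the list alone without the replicate block but not with it, where Hspa1a of the heat shock list passed. Acinar markers differed by 0.90 with 13 of 13 positive and cell cycle genes by 0.33 with 8 of 8 positive. The adjusted p was 2.10e-07, 1.57e-05, 0.000141, 2.02e-06 and 0.000358, and with an estimated correlation the adjusted p was 0.381, 0.199, 0.199, 0.381 and 0.285. White adipocyte markers differed by -0.48 with 12 of 12 negative and cholesterol synthesis by 0.20 with 7 of 12 positive. Their adjusted p was 0.000388 and 0.0125, and both had adjusted p = 0.381 with an estimated correlation. The adipocyte call ended without young female eET-1 replicate 1 or wild-type replicate 2 (up to 0.180). The cholesterol call ended without young female eET-1 replicate 2 or wild-type replicate 3 or 4 or mature female eET-1 replicate 4 or wild-type replicate 2 or 3 (up to 0.202), and with no filter on dim probes. Genes of smallest p were the NF-kappaB members Relb at 0.77 (SE 0.24) and Nfkbie at 0.88 (SE 0.28), the kinase Prkcd at 0.51 (SE 0.17), Kdm8 at 0.59 (SE 0.21) and Cnot9 at 0.50 (SE 0.19), with Mgat1 at -0.79 (SE 0.23), Kank3 at -0.56 (SE 0.17), Ranbp9 at -0.88 (SE 0.29) and Tbc1d10b at -0.64 (SE 0.22) on the negative side. Limma called 0 of 8386 genes, with 125 at an unadjusted p under 0.05 (317 with the block). Camera called 16 lists, 11 with the replicate block and 10 among probes detected on all arrays of a cohort, and the fatty acid, heat shock, glucocorticoid, acinar and cell cycle lists were called under every omission of 1 array.

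In young mice, camera at the preset correlation called sterol and glucocorticoid genes for a sex difference in their genotype difference. Female minus male, cholesterol synthesis differed by -0.60 with 12 of 12 members negative. Sqle at -1.22 (SE 0.30), Hsd17b7 at -0.96 (SE 0.25), Msmo1 at -0.99 (SE 0.32) and Hmgcs1, the enzyme before the rate-limiting step, passed when adjusted over the list alone (with the replicate block Cyp51 and Sc5d too). The glucocorticoid list differed by 0.98 with 5 of 6 members positive, and Fkbp5 at 2.62 (SE 0.67) and Sult1a1 passed when adjusted over the list alone (with the block Mt1 and Mt2 too). Clock outputs differed by 1.30 with 8 of 8 positive. The adjusted p was 1.49e-08, 0.000254 and 0.000752, and with an estimated correlation the adjusted p was 0.142, 0.192 and 0.578. Permutation of the genotype labels gave p = 0.0241 for cholesterol synthesis and 0.0314 for the glucocorticoid list, neither passing adjustment over the lists. Clock activators differed by -1.27, smooth muscle by -0.19 and hypoxia genes by -0.26, with adjusted p = 0.00912, 0.00912 and 0.0183 and, with an estimated correlation, adjusted p = 0.306, 0.720 and 0.306. The activator call ended without young female wild-type replicate 2 or young male eET-1 replicate 4 (up to 0.0593). The smooth muscle call ended without either of these or young male wild-type replicate 1 (up to 0.264), and the hypoxia call without either of these or young female eET-1 replicate 2 or wild-type replicate 4 (up to 0.121) and with no filter on dim probes. Among probes detected on all 8 arrays the glucocorticoid call ended. Other genes of small p were H6pd, which makes NADPH in the endoplasmic reticulum, at 0.79 (SE 0.20), Hes1, a Notch target, at 0.61 (SE 0.18), Wipi1 at 0.58 (SE 0.19), Tnfrsf22 at -0.90 (SE 0.25) and Prkdc at -0.65 (SE 0.21). Limma called 0 of 8386 genes, with 209 at an unadjusted p under 0.05 (507 with the block).

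Across genes, the log2 differences of young males and mature males had a Pearson correlation of 0.35 (Spearman 0.20), with permutation p = 0.0596. It was 0.215 without young male eET-1 replicate 1. Young females correlated with both male cohorts at 0.32, with young males at 0.0686 without young male eET-1 replicate 4 and 0.198 without young female wild-type replicate 3, and with mature males at 0.161 without young female eET-1 replicate 1. Mature females correlated with young females at -0.17, with young males at -0.20 and with mature males at -0.30, and without mature female wild-type replicate 4 these were 0.0725, -0.0272 and -0.0904. The 6 permutation p values ran from 0.0596 to 0.549 and their adjusted values from 0.186 to 0.549, so no pair passed. Genes are not independent replicates, and the permutations split the arrays of both cohorts.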

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

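Chosen after the result was seen were the 9 tests of gene counts over other splits, the tests of adipocyte RNA, the smooth muscle test with age, and the list tests of differences between cohorts.

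Of 162 groups of 4 arrays tested, 17 held an array far from the other 3, where chance gives 8, or 1 in 20. Median signal was 176.7 on young male wild-type replicate 4 and 128.9 to 129.5 on the others. Detected probes numbered 12545 on young male eET-1 replicate 4 (others 12176 to 12193) and 11342 on young male wild-type replicate 3 (12016 to 12093). The highest signal was 48400 on mature female eET-1 replicate 4 (others 56170 to 56560). Young female eET-1 replicate 2 had scores of -0.732 for fatty acid synthesis (others 0.481 to 0.692) and -0.561 for brown adipocyte markers (0.388 to 0.498). In mature females, wild-type replicate 2 had a cell cycle score of -0.408, and eET-1 replicate 3 scores of -0.600 for acinar and 0.152 for endothelial markers. In young males, eET-1 replicate 4 had 0.860 for clock activators and 12.47 for Ednra (others 11.14 to 11.33), and wild-type replicate 4 had -0.455 for acinar markers. In mature males the wild types stood out with -0.521 for cholesterol synthesis (replicate 2), -0.0806 for vascular tone (replicate 1), -0.764 for adipocyte markers (replicate 4) and -0.0273 for nerve markers (replicate 3), and Edn1 read 9.533 on eET-1 replicate 4 (others 10.91 to 11.16).

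Of 132 tests of a list's difference between cohorts by permutation, 7 had p under 0.05, where chance gives 7. At maturity, female minus male, these were fatty acid synthesis at -1.18, adipocyte markers at -0.777 and antioxidant genes at -0.211. The antioxidant call of camera (adjusted p = 0.00716, and 0.305 with an estimated correlation) ended without mature female eET-1 replicate 3 (0.0583), with median centring and with no filter on dim probes. In males, mature minus young, smooth muscle differed by -0.441, and in females the glucocorticoid response by -0.823. In youth, female minus male, cholesterol synthesis differed by -0.604 and the glucocorticoid response by 0.981.

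Fatty acid and triglyceride synthesis genes were higher in eET-1 arteries by a mean of 0.454 (SE 0.167) over the cohorts. Adipocyte RNA is left open. The list's signed mean lay above that of adipocyte markers by 0.317 (permutation p = 0.0169), but in mature females, where both were lower, the list moved less far than the markers. The distances moved differed by 0.383, -0.145, 0.195 and 0.546 in young females, mature females, young males and mature males, with a mean of 0.245 (one-sided permutation p = 0.0501). Within single cohorts the signed difference did not pass (0.383, 0.162, 0.210 and 0.601, exact permutation p = 0.286, 0.514, 0.400 and 0.0857). These permutations did not keep like-numbered arrays as pairs. Adipocyte transcripts were abundant although fat was removed, with Adipoq at a cohort mean of 13.28 to 13.84, and the 2 lists share no gene. With the clock output score as a linear covariate the difference was 0.421 (SE 0.171), so a shared linear dependence on that score did not account for most of it. Over 32 arrays the scores had Pearson r = -0.189 (permutation p = 0.386), Spearman -0.201 (p = 0.324), and r = -0.209 without the 2 farthest arrays. Clock outputs moved up in young females and down in males, and 1 slope over the cohorts cannot follow a cyclic phase. Clock phase is left open. In mature males the age gap could contribute: with age as a covariate the difference of 0.987 (SE 0.344) was 0.948 (SE 0.611), which leaves it open, and an effect of genotype stays open as well.

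Smooth muscle contractile genes were lower in mature male eET-1 arteries by -0.215 (SE 0.0939). With age as a covariate the difference was -0.0747 (SE 0.146), so the call ended as the estimate shrank and its error grew, and the younger age of the eET-1 mice may account for it. A lower share of smooth muscle RNA cannot be told apart from it: the other 12 cell types ranged over 1.53 (exact permutation p = 0.171), 6 moving up and 6 down. An effect of genotype on these genes was not separable from age.

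Pancreatic acinar genes differed between arrays of 1 group. Their 13 members had a mean pairwise correlation of 0.885 over 32 arrays within groups, where 2000 random lists of like level had a median of 0.0557 and a highest of 0.416. Pancreatic tissue in some samples is a candidate source, and the labels name removal of fat alone. In mature males the amylase gene Amy2 read 14.23 ± 0.69 in eET-1 and 14.62 ± 0.51 in wild-type arrays (SD, n = 4), and Clps, colipase, 13.54 ± 0.85 and 14.41 ± 1.03. Array scores ran from -1.67 to 1.57, both in mature males. No biological explanation was tested.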

How the results depend on the processing

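Chosen after the data were seen were the young female array sets, the cohort differences taken from the joint fit, the omissions of arrays for the correlations and, for the lists, each omission and setting but the estimated correlation and fry. Limma called 0 genes in each of the 9 comparisons under every setting except those given here, and the cause was not tested. Array weights gave 9 genes in mature males, and omissions 0 to 85, the highest without eET-1 replicate 1. In the mean of the cohorts the block gave 1, an adjusted p under 0.10 gave 1, and omissions 0 to 2. The joint fit of all 32 arrays gave 0 genes in each cohort, and with the block 2 in mature males (Plin2 and Cldn10), where numbers do not pair the arrays. An unadjusted p under 0.01 with 1.5-fold gave 10, 10, 13, 99 and 11 genes in young females, mature females, young males, mature males and the mean of the cohorts, and 26, 12, 11 and 21 for sex at maturity, age in males, age in females and sex in youth.

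Lists called were 0 in all 9 comparisons with an estimated correlation and 0 with fry. The estimated correlation sets the error by how far list members vary together on these arrays. In simulated data with genes drawn independently, it called a list moved by 0.5 in each cohort but young females. Genes there do not vary together, so this cannot show how often it finds such a shift on the real arrays. At the preset correlation the moved list was called in each cohort, and in young females 1 unmoved list was called too. Omitting 1 array gave 8 to 15 lists in young females, 8 to 13 in mature females, 7 to 13 in young males, 4 to 11 in the mean of the cohorts, 10 to 20 for sex at maturity, 3 to 8 for age in males, 8 to 16 for age in females and 3 to 11 for sex in youth. Young female replicates 1 and 3 alone gave 5, the mean without young males 4, detection on all 8 arrays 10 for age in females, and median centring 10 for sex in youth. In mature males like-numbered arrays correlated at 0.311, -0.0961, 0.171 and -0.294, so numbers do not pair them, and the block there added lymphocyte markers (adjusted p = 0.0368) and extracellular matrix (0.0287). In the age difference of females the block ended the endothelial, macrophage, antioxidant, fatty acid oxidation and brown adipocyte calls (each 0.0605). Among list calls the block changed none beyond these and those in the report. In mature males with the block 0 smooth muscle genes, 13 genes of cholesterol synthesis and Rgs5 of vascular tone passed over the list alone. For lists not called, the block moved 1 or 2 members past that threshold or back (Nox4, Thbs1 and Ldha, for example).

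Correlations of cohort differences with 1 array omitted ran from -0.283 to 0.0725 (young with mature females), 0.0686 to 0.382 (young females with young males), 0.161 to 0.368 (young females with mature males), -0.292 to 0.0804 (mature females with young males), -0.461 to -0.0904 (mature females with mature males) and 0.215 to 0.401 (young with mature males). With no filter on dim probes the last was 0.297 (permutation p = 0.0384, and 0.230 when adjusted over the 6 pairs).

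Of 7628 values of 310 named results, 7551 kept direction and stayed short of the threshold, 30 came to pass it and 47 reversed. No named gene passed in the main fit, so none could lose a call. Many were picked for small p, which favours a kept direction. Omitting an array outside the cohorts of a difference leaves its size unchanged, so the 7551 is no measure of stability. In young females Ednra was 0.0767 with median centring and 0.00542 with array weights, Ece2 -0.0297 with weights and -0.00548 with age, Ece1 -0.0421 and Cox7a1 -0.0167 with age. In young males array weights gave Phex -0.144, Ednrb -0.0538, Ednra -0.189, Ece2 0.0376, Try4 0.00404 and Cpa1 0.0268. In mature males Sdhb was -0.000755 with age. Omissions ranged, in young females, from -0.116 to 0.0676 for Ednra, -0.0116 to 0.0973 for Ece1, -0.113 to 0.129 for Ece2, -0.0254 to 0.235 for Cox7a1, -0.526 to 0.0180 for Cd79b and -0.225 to 0.00350 for Phex. In mature females they ranged from -0.177 to 0.0329 for Ednra, -0.102 to 0.242 for Ece2 and -0.0735 to 0.267 for Phex. In young males they ranged from -0.130 to 0.193 for Phex, -0.0147 to 0.606 for Hbb-b2, -0.173 to 0.454 for Hbb-b1, -0.0905 to 0.987 for Cidea, -0.00417 to 0.333 for Ednrb, -0.228 to 0.216 for Ednra, -0.514 to 0.0919 for Ece2, -0.646 to 0.00862 for Try4 and -0.339 to 0.0583 for Edn1. In mature males Ece1 ran from -0.0892 to 0.0204, while a dimmer Ece1 probe had group means of 7.638 in eET-1 and 8.095 in wild-type arrays. Signal over background limits dim genes, since Edn2, Edn3 and Kel lay at background on all arrays.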

Other observations

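Chosen after the result was seen were the look at genes called without a single array, the 9 tests of gene counts over other splits, the test of the highest count over omissions and the splits that part like-numbered pairs in several cohorts.

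Without eET-1 replicate 1, whose fatty acid synthesis score was -0.49, mature male arteries had 85 genes past limma's adjusted p of 0.05, 66 higher and 19 lower in eET-1 (84, of which 65 higher, once Mod1, an older symbol of Me1, is counted with it). All 85 had the same sign with every array, but they were chosen on most of those same arrays, so this is no further evidence. Of the 85, 10 belong to fatty acid synthesis and 7 to cholesterol synthesis. Thrsp, a lipogenic nuclear protein, lay at 2.56 (1.82 with every array) and Elovl6, an elongase, at 2.61 (2.02 with every array). Me1, at 1.65, is 1 of the 10. Slc25a1, which exports citrate from mitochondria, was higher by 1.47, Pcx, pyruvate carboxylase, by 1.47, Aacs by 1.66, G6pdx by 0.70, Pgd by 0.99 and Idh1 by 0.62. Tkt, transketolase, was higher by 1.17 and Pygl, glycogen phosphorylase, by 1.15. Ptger3, a prostaglandin E2 receptor, was higher by 1.06. Lower genes included the chemokine Ccl19 at -0.89, Abcc9 at -0.53 and Cyp1b1 at -0.58. The 9 genes that array weights called, all lower, lay within the 85: Tpcn2, Clic1, Dynll2, Chst8, Pim3, Nacad, Crim1, Kcnip3 and Lrfn3. Among splits of the 7 arrays, 1 of 35 gave as many genes, the real one, and the highest other gave 4, but this array was picked for its count and the other splits had no such pick. With every split of the 8 arrays given its best omission, 2 of 35, the real one included, gave as many, the highest other reaching 91, so chance cannot be excluded for this count.

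Over splits of all arrays of a cohort, 0 genes were called by the real split and so all 35 gave as many, with a highest other of 3246 in young females, 7 in mature females, 42 in young males and 7 in mature males. The split with 3246 set replicates 1 and 3 against 2 and 4, which points to a structure of the samples in young females. Taking that array set as a block gave 0 genes. For the mean of the cohorts, sex at maturity, age in males, age in females and sex in youth, all 100 splits drawn gave as many, with a highest other of 680, 17, 1, 1684 and 2025. Mature males had 1077 genes at an unadjusted p under 0.05, and 2 of 35 splits, the real one included, gave as many, the highest other being 1083.

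For lists, the 13 called in young females were matched by 2 of 35 splits (highest other 14), the 8 in mature females by 24 (17), the 12 in young males by 5 (16) and the 9 in mature males by 19 (16), so chance cannot be excluded for any of these counts. Every number of matching splits, here and below, includes the real split. Of the 8 splits that part every like-numbered pair, 2, 5 and 2 gave as many lists in young females, mature females and young males, with up to 14, 10 and 13 lists, and the other splits gave up to 12, 17 and 16. Of 100 splits drawn, 43 matched the 7 lists of the mean of the cohorts (highest other 15), 60 the 6 of age in males (18) and 37 the 6 of sex in youth (13), which does not exclude chance. For sex at maturity 2 matched the 18 lists (highest other 18), and for age in females 2 matched the 16 (16). Of 100 splits that part every like-numbered pair outside mature males, 1 matched the 18, the real one (highest other 17), and 3 the 16 (17). The counts of the mean of the cohorts, age in males and sex in youth were matched by 55, 63 and 52. The shares of sex at maturity and age in females are the 2 smallest of 9 and were not adjusted for the 9 comparisons. Chance is thus not excluded for either count or for any single list. The counts hold at the preset correlation, and with an estimated correlation both were 0. They were 10 without mature female eET-1 replicate 3 and 8 without mature female eET-1 replicate 4, and age in females had 11 with the block and 10 among probes detected on all 8 arrays. Of 132 permutation tests of list differences 7 had p under 0.05, where chance gives 7, and none passed adjustment.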
